A study of Mus musculus with 2 samples.

How the data were processed

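Bulk RNA sequencing was done on interscapular brown adipose tissue of male-labelled, 1-month-old C57BL/6J mice. There were 2 libraries. The control library was made from the pooled tissue of 3 littermates and the Rheb knockout library from that of 3 mice in which, per the labels, a Cre recombinase under the Ucp1 promoter deletes Rheb in brown adipocytes. Libraries were prepared from Trizol-extracted RNA with the TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark the strand of the transcript, so reads of overlapping genes on opposite strands cannot be told apart.

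The deposited table holds raw read counts per gene for each library, with no normalization. Per the submitters' processing notes, the reads went through Trimmomatic, HISAT2 and featureCounts with the mm10 mouse genome build; the versions, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Per the file headers, each of the 54532 rows is an Ensembl gene with its coordinates and a length in bases, which was not used. Coordinates are given here as the table gives them, on mm10. The table's transcript type belongs to a single transcript, so gene types were taken from GENCODE release M21, a GRCm38 annotation, which matched 54495 of the gene identifiers. In the symbol column 27 entries had been turned into dates, and these were not repaired. Where a symbol stood for more than 1 identifier (102 symbols), it was read as the identifier with more counts.

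Each group is 1 library, so the spread between mice cannot be measured and no difference has a replicate check. No p-value was computed. Counts were turned into CPM (counts scaled to a common library size) with TMM factors from edgeR 4.0.16. The ratio of the knockout over the control library was taken as log2 of CPM plus a pseudocount of 0.5, which understates the change of low genes. Folds of single genes are ratios of scaled counts without the pseudocount, with a 95% exact binomial (Clopper-Pearson) interval. These intervals cover counting error only, and PCR copies are not independent molecules. Against a library at 0 counts, a fold was computed with a floor of 3 counts in that library, and the lower end of the interval is given beside it. Genes with a mean of at least 1 CPM over both libraries were kept (12973 genes).

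The following choices were made before the data were examined. A gene counted as higher or lower by size where its log2 ratio reached 2-fold and its interval excluded 1. There were 37 gene lists with 707 symbols, of which 705 were found in the table. A list member counted as higher or lower at 1.5-fold with an interval that excluded 1, and as in between otherwise. For each of the 35 lists with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart under percentile 2.5 or over percentile 97.5. These percentiles describe the 2 libraries and are not p-values. If genes varied independently, about 1.75 of the 35 lists would stand apart by chance. The genes named are Rheb, Rhebl1 and Ucp1, the 10 largest and 10 smallest ratios among genes with a mean of at least 10 CPM (without predicted models and antigen receptor segments), and up to 4 members of each list with the largest absolute ratio. Some genes that this rule takes are not reported here. All other genes named, among them genes that overlap a named gene (Naxd, Mterf4), members whose removal moved a list most (mt-Atp6, Atp6v1h), the muscle genes Acta1 and Ckm and the members of families, were chosen after their values were seen.

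The alternatives were other filters (none beyond 1 read, or 10 CPM), pseudocounts of 0.05 and 2, protein-coding genes only, DESeq2 1.42.0 size factors, total counts with and without the 20 genes with the highest counts, fold thresholds of 1.5 and 3, random lists without expression matching, and leaving out each list member. Corrections for GC content and counts without sex chromosomes or mitochondrial genes were added after the data were seen. GC content was that of the longest GENCODE transcript and was available for 99.9% of the kept genes. Alternatives that need the authors' normalized values or calls could not be run, because the table used here holds counts.

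The size rule was tested on simulated counts with the real means and library sizes. It recovered 100% of 53 genes set 4-fold lower and of 52 set 4-fold higher, 93.6% of 47 genes set 2.5-fold higher and 87.0% of 46 genes set to 0.4 of the control level, and called none of 12791 unchanged genes. The intervals held the true ratio for 95.7% of 12989 simulated genes. These simulations hold counting noise only. With the real spread of ratios, 5.5% of 200 random lists of 20 genes stood apart, and 98.5% did with a planted shift of 0.8 on the log2 scale. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.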

Results

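Gene expression was measured by RNA sequencing in interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, of 1-month-old mice. The design asks which transcripts differ when Rheb, the small GTPase that activates the mTORC1 kinase complex, is deleted in brown adipocytes. Each group was 1 library from a pool of 3 mice, so every value below describes 2 libraries and has no replicate error. The control library held 21855229 counts over 20887 detected genes, and the Rheb knockout library held 23699316 counts over 19457 detected genes. Mitochondrially encoded genes took 20.99% of the control counts and 27.6% of the knockout counts. A further 10.2% and 14.7% lay on 4 chromosome 1 pseudogenes that resemble mitochondrial genes. Reads of these genes may be shared between copies, which was not tested, so their levels are uncertain.

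Rheb (ENSMUSG00000028945, chromosome 5, 24802823 to 24842624, minus strand, mm10) was lower in the knockout library, which is labelled as the deleted group. It had 1037 counts (45.3 CPM) in the control library and 568 counts (25.1 CPM) in the knockout library, a ratio of 0.553 (95% counting interval 0.499 to 0.613). The counts cover the whole gene and all cells of the tissue, so they do not separate deleted from intact exons or brown adipocytes from other cells. Rhebl1, a Rheb paralog, was low in both libraries, with 46 counts in the control and 72 in the knockout library, a ratio of 1.58 (1.08 to 2.34).

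Sex-linked transcripts went against the label of the control library, since both libraries are labelled male. Xist, the RNA that coats the inactive X chromosome of females, had 7452 counts in the control library and 4 in the knockout library, 1845-fold lower in the knockout library (720.1 to 6772). Eif2s3y had 0 counts in the control library against 2653, 893-fold higher in the knockout library with the floor of 3 counts. Ddx3y had 0 against 1484, 499.6-fold higher with that floor. The lower ends of their counting intervals were 725.8-fold and 405.8-fold. Uty, also Y-linked, had 1 count against 431. All 5 genes of the sex marker list passed the 1.5-fold size rule, 4 higher and 1 lower in the knockout library, with a median log2 ratio of 5.17, the value of Uty, above all 10000 random lists. Every difference below is therefore a difference in genotype label and in sex-linked expression at once.

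Among 12973 genes, 1201 were at least 2-fold higher and 1294 at least 2-fold lower in the knockout library. With plain total-count scaling, which lowered the median log2 ratio of all genes from -0.003 (TMM) to -0.13, the split was 887 higher and 1671 lower. At the 1.5-fold rule used for list members, with TMM scaling, 2839 of the 12973 genes were higher and 2839 lower. Counts of list members below are to be read beside that share. Besides the Y-linked genes, the largest ratios belonged to Cars2, the mitochondrial cysteinyl-tRNA synthetase (988 and 8376 counts, 8.56-fold higher, 8.01 to 9.15), Cntfr, a receptor subunit for ciliary neurotrophic factor (87 and 751 counts, 8.72-fold higher), and the zinc finger gene Zfp653 (7.83-fold, 7.02 to 8.77). Slco4a1, an organic anion transporter, was 7.10-fold higher, Epn3 7.21-fold, Sned1 6.78-fold and Adamtsl5 6.46-fold. The span of Cars2 overlaps Naxd on the other strand, which had 1274 and 1417 counts, and that of Sned1 overlaps Mterf4, with 415 and 199 counts. Among the 10 smallest ratios were those of Xist and of the muscle genes Myh7 (4223 and 69 counts, 60.6-fold lower in the knockout library, 47.8 to 78.0), Tnni1 (28.7-fold lower), Myl2 (26.7-fold lower), Mybpc1 (21.3-fold lower) and Mb, myoglobin (20.2-fold lower). Adprhl1 had 682 counts in the control library and 4 in the knockout library (169-fold lower, 65.6 to 621). The major urinary protein genes Mup10 and Mup11 were 44.0-fold and 49.8-fold lower, but their near-identical paralogs make the assignment of reads to single members uncertain. The stearoyl-CoA desaturase gene Scd2 was 19.1-fold lower (17.6 to 20.7).

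**Figure D1:**
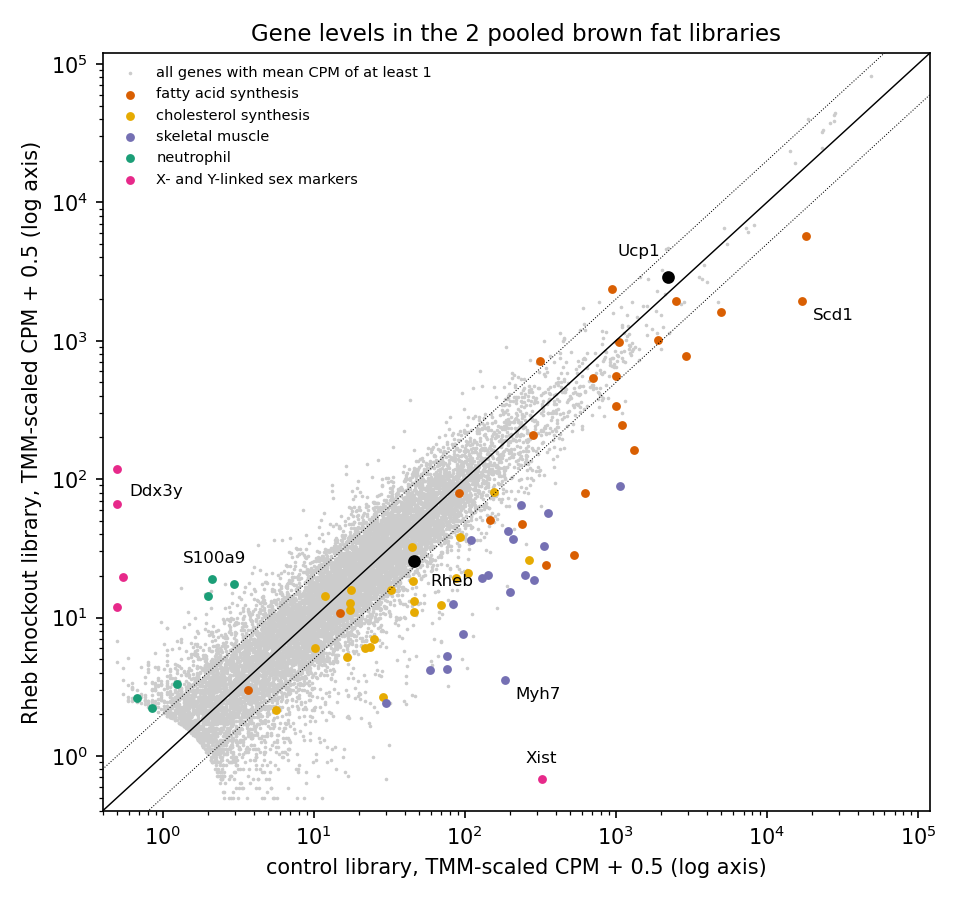
Level of each gene in the control library (horizontal) against the Rheb knockout library (vertical), in TMM-scaled CPM plus 0.5 on log axes; grey points are the 12973 genes with a mean of at least 1 CPM, coloured points are members of 5 gene lists, black points are Rheb and Ucp1, the solid line marks equal levels and dotted lines 2-fold differences. Scd1 and most other lipid synthesis genes and all skeletal muscle genes lie below the diagonal, Xist and the Y-linked genes lie at opposite edges, and Ucp1 lies slightly above the diagonal at a ratio of 1.31.

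Genes of lipid synthesis were lower in the knockout library. Of 23 measured genes of fatty acid synthesis, 14 were lower, 2 were higher and 7 lay in between, with a median log2 ratio of -1.53, below all 10000 random lists. Scd1, the desaturase that makes oleate, had 17163 CPM in the control and 1924 CPM in the knockout library, 8.92-fold lower (8.83 to 9.01). Pnpla3, a lipid droplet protein, was 14.7-fold lower and Slc25a1, the mitochondrial citrate carrier, 8.15-fold lower. Fasn, fatty acid synthase, chosen after its values were seen, was 3.18-fold lower (3.16 to 3.20). The 2 members that were higher, also named after their values were seen, encode transcription factors of this pathway, Srebf1 (log2 ratio 1.18) and Mlxipl (1.32). In cholesterol synthesis, 18 of 22 measured genes were lower and none was higher, with a median of -1.54, below all 10000 random lists. Insig1, a sterol-regulated protein of the endoplasmic reticulum, was 10.3-fold lower (9.50 to 11.3), Nsdhl 5.78-fold and Sc5d 5.13-fold. Breakdown of branched-chain amino acids gave 14 lower, 1 higher and 5 in between of 20 genes and a median of -1.15, below all 10000 random lists. Bckdha, a subunit of the branched-chain ketoacid dehydrogenase, was 5.32-fold lower, Pcca 5.03-fold and Mut 3.35-fold, while Bckdhb (named after its value was seen) had a log2 ratio of 1.02. Skeletal muscle transcripts, at 0.431% of counts in the control and 0.0462% in the knockout library, moved with these groups.

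Lists of nuclear genes of fuel use had medians below 0, with most members of several lists in between, while the list of mitochondrially encoded genes had a median above 0. Of 24 genes of fatty acid oxidation, 13 were lower and 3 higher, with a median log2 ratio of -0.65 (percentile 0.030). Acadvl, the very-long-chain acyl-CoA dehydrogenase, was 2.76-fold lower and Cpt2, which regenerates acyl-CoA inside mitochondria, 2.74-fold. In the tricarboxylic acid cycle 8 of 17 genes were lower and none higher (median -0.57, percentile 0.98), with Idh3b 2.88-fold and Fh1 2.28-fold lower. Nuclear genes of the respiratory chain had 11 of 36 lower, 1 higher and a median of -0.42 (percentile 1.30), with Uqcrc2 2.61-fold and Ndufa9 1.98-fold lower. In glycolysis and glucose uptake 7 of 21 genes were lower and none higher (median -0.49, percentile 1.69), led by the muscle isoform gene Pfkm (2.60-fold lower) and Pgam1 (2.49-fold); without Pfkm the percentile was 6.39. Of the 13 mitochondrially encoded genes 4 were higher, none was lower and 9 lay in between, with a median of 0.49 (percentile 98.0), with mt-Nd3 2.11-fold and mt-Co1 1.68-fold higher; this list no longer stood apart without a filter (97.4), without expression matching (97.1) or without mt-Atp6 (95.9). Skeletal muscle also expresses the genes of these lists, mitochondrially encoded ones included, and its markers took 0.431% of the control and 0.0462% of the knockout counts. Whether muscle RNA contributed to the differences of these lists was not tested.

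The thermogenic program did not stand apart as a group. Ucp1 (chromosome 8, 83290352 to 83298452, plus strand), the proton channel of brown fat mitochondria, had 50564 counts in the control and 65375 in the knockout library, a ratio of 1.31 (1.29 to 1.32). Of 26 measured thermogenic genes 6 were higher, 8 lower and 12 in between, and the median of 0.03 lay at percentile 65.3; its sign turns with total-count scaling (-0.09). Dio2, the deiodinase that activates thyroid hormone, was 4.06-fold higher (3.89 to 4.24) and the coactivator Ppargc1b 2.72-fold higher, whereas Adrb3, the beta-adrenergic receptor of adipocytes, was 3.75-fold lower (3.54 to 3.99) and S100b, also a Schwann cell marker, 2.74-fold lower. Genes of cAMP-PKA signalling went both ways, with 8 of 25 higher and 5 lower and a median of 0.23 (percentile 91.1). The phosphodiesterase genes Pde4d and Pde10a were 2.23-fold and 2.21-fold higher and the adenylyl cyclase Adcy4 2.20-fold higher. This list stood apart without a filter (97.8), but its median was -0.01 (percentile 50.7) with a filter of 10 CPM. In the Notch pathway 6 of 22 genes were higher and 1 lower (median 0.28, percentile 93.4, and 97.6 at a filter of 10 CPM). Notch3, a receptor that also marks pericytes and smooth muscle, was 3.18-fold higher (2.91 to 3.49) and the ligand Jag2 2.54-fold higher.

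Components of the mTORC1 pathway were lower as a list, with 11 of 27 lower, 4 higher and a median of -0.46 (percentile 0.22). The list contains Rheb, and without it the percentile was 0.68. Skeletal muscle markers were lower in the knockout library as well, with a median of -3.58. Rragd, a Rag GTPase of the lysosomal amino acid sensor, was 6.47-fold lower (98 and 15 counts, 3.74 to 12.0), the mTOR inhibitor Deptor 3.22-fold lower, and the translational repressors Eif4ebp1 and Eif4ebp2 3.15-fold and 2.78-fold lower. Of 32 genes of lysosome and autophagy 13 were lower and 5 higher (median -0.33, percentile 1.95, and 5.46 at a filter of 10 CPM). Ctsb, a lysosomal protease, was 3.70-fold lower and Npc2, a lysosomal cholesterol carrier, 2.90-fold lower, while Flcn, which encodes folliculin, was 2.94-fold higher and Gpnmb, with 7 and 94 counts, 13.6-fold higher (6.33 to 34.7). Cytosolic ribosomal protein genes were higher in 16 of 37 cases and lower in none, with a median of 0.49, above 9994 of 10000 random lists; Rpl38 was 2.38-fold and Rps20 1.86-fold higher. The ATF4 and amino acid stress list gave 4 higher and 6 lower of 25 (median -0.12, percentile 26.7), with the stress hormone gene Gdf15 at 9 and 59 counts and the serine synthesis gene Psph 3.20-fold lower. Endoplasmic reticulum chaperones gave 1 higher and 5 lower of 20 (median -0.28, percentile 5.94), with Dnajb9 1.89-fold lower.

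Other adipocyte lists did not stand apart. Lipolysis and lipid droplet genes had 2 of 21 higher and 4 lower (median -0.27, percentile 15.4), with Plin4, a droplet coat protein, 2.12-fold higher and Fitm1 5.67-fold lower. White adipocyte and adipokine genes had 3 of 13 higher and 6 lower (median -0.10, percentile 36.2), with the retinol carrier Rbp4 4.39-fold and the natriuretic peptide clearance receptor Npr3 4.21-fold lower; at a filter of 10 CPM this list had a median of -0.73 and lay at percentile 0.42. In the list of creatine, calcium and other cycling without UCP1, 5 of 12 were lower and 2 higher (median -0.28, percentile 16.0). Its members with the largest ratios, Atp2a1 (15.8-fold lower), Ckmt2 (12.4-fold) and Sln (14.2-fold), are also muscle genes.

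Markers of other cell types differed between the libraries. All 19 measured skeletal muscle genes were lower in the knockout library, with a median log2 ratio of -3.58, below all 10000 random lists, and the fast muscle genes Atp2a1 and Myh2 were each 15.8-fold lower. Neutrophil, erythroid and macrophage markers were higher in the knockout library. All 6 neutrophil genes that passed the filter were higher (median 2.26, above all 10000 random lists), with S100a9 at 37 and 415 counts (11.3-fold, 8.08 to 16.3) and S100a8 9.30-fold higher. Without the filter 8 of 12 were higher and 1 lower (median 1.33, above all random lists), and a pseudocount of 2 gave a median of 1.51 and one of 0.05 a median of 2.97. Of the erythroid genes 5 of 6 were higher (median 1.34, above all random lists), with the globin gene Hba-a1 2.86-fold and Hbb-bs 2.47-fold higher. With no filter beyond 1 read, 7 of 9 erythroid genes were higher and none lower (median 1.19). Of 17 macrophage genes 11 were higher and 1 lower (median 1.01, above all random lists), including the scavenger receptor Cd163 (3.12-fold) and the complement gene C1qb (2.59-fold). Of 13 B cell genes only the antibody genes Igkc (7.36-fold higher), Ighm (3.32-fold) and Jchain (2.83-fold) passed the filter. Without it 3 were higher, 4 lower and 6 in between, and the median was -0.42 (percentile 7.16). None of the 18 T and NK cell genes had a mean of 1 CPM, and without the filter 3 were higher and 5 lower (median -0.28, percentile 7.26).

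Stromal and nerve markers were also higher in the knockout library. Fibroblast and preadipocyte genes were higher in 9 of 15 cases and lower in none (median 0.79, above 9995 of 10000 random lists), with Gli1 at 19 and 140 counts (7.44-fold) and Pdgfrb 3.03-fold higher. This list lay at percentile 93.5 with a filter of 10 CPM. Extracellular matrix genes were higher in 13 of 24 cases and lower in 1 (median 0.67, above 9997 of 10000 random lists), among them Eln, elastin (5.29-fold, 4.85 to 5.78), the matrix protease Mmp14 (3.63-fold) and the collagen gene Col6a1 (3.20-fold). Of 9 smooth muscle and pericyte genes 5 were higher and 1 lower (median 0.77, percentile 99.7, and 95.4 with a filter of 10 CPM). Cnn1 was 8.24-fold and Acta2 5.60-fold higher, while Des, which skeletal muscle also expresses, was 3.79-fold lower. Schwann cell and neuron genes gave 8 higher and 1 lower of 9 (median 0.90, percentile 99.8), with Prx 4.12-fold higher. With no filter beyond 1 read, 9 of 13 of these genes were higher, 1 was lower and 3 lay in between (median 0.80). Endothelial genes were higher in 4 of 15 cases and lower in none (median 0.28, percentile 89.1), with Vwf 3.42-fold higher.

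Among lists that follow the state of the tissue, the immediate early genes stood apart in every setting run. They were higher in 12 of 22 cases and lower in 4 (median 0.61, above 9996 of 10000 random lists), led by the nuclear receptor genes Nr4a2 (892 and 5006 counts, 5.67-fold, 5.28 to 6.09) and Nr4a1 (4.41-fold), with Btg2 2.44-fold lower. Morning-phase clock genes were higher in 3 of 5 cases (median 0.80, percentile 98.4), with Npas2 3.26-fold and Arntl 1.91-fold higher, and without Arntl the percentile was 76.0. Evening-phase clock genes gave 4 higher and 2 lower of 10 (median 0.34, percentile 88.6), with Per1 2.19-fold higher and Nr1d1 2.73-fold lower. Class II antigen presentation gave 4 lower and 2 higher of 8 (median -0.64, percentile 2.21, and 11.7 without H2-Aa), with H2-Aa 3.81-fold lower. Interferon response genes gave 8 higher and 5 lower of 20 (median 0.15, percentile 77.7), with Stat2 2.57-fold higher and Cxcl9 5.06-fold lower. Of 12 measured cell cycle genes 5 were higher and 2 lower (median 0.17, percentile 73.3), with Mki67 at 21 and 77 counts; with a filter of 10 CPM 1 gene was left, with a log2 ratio of -0.22. In all, 12 lists stood above, 11 below and 12 within the range of random lists.

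**Figure D2:**
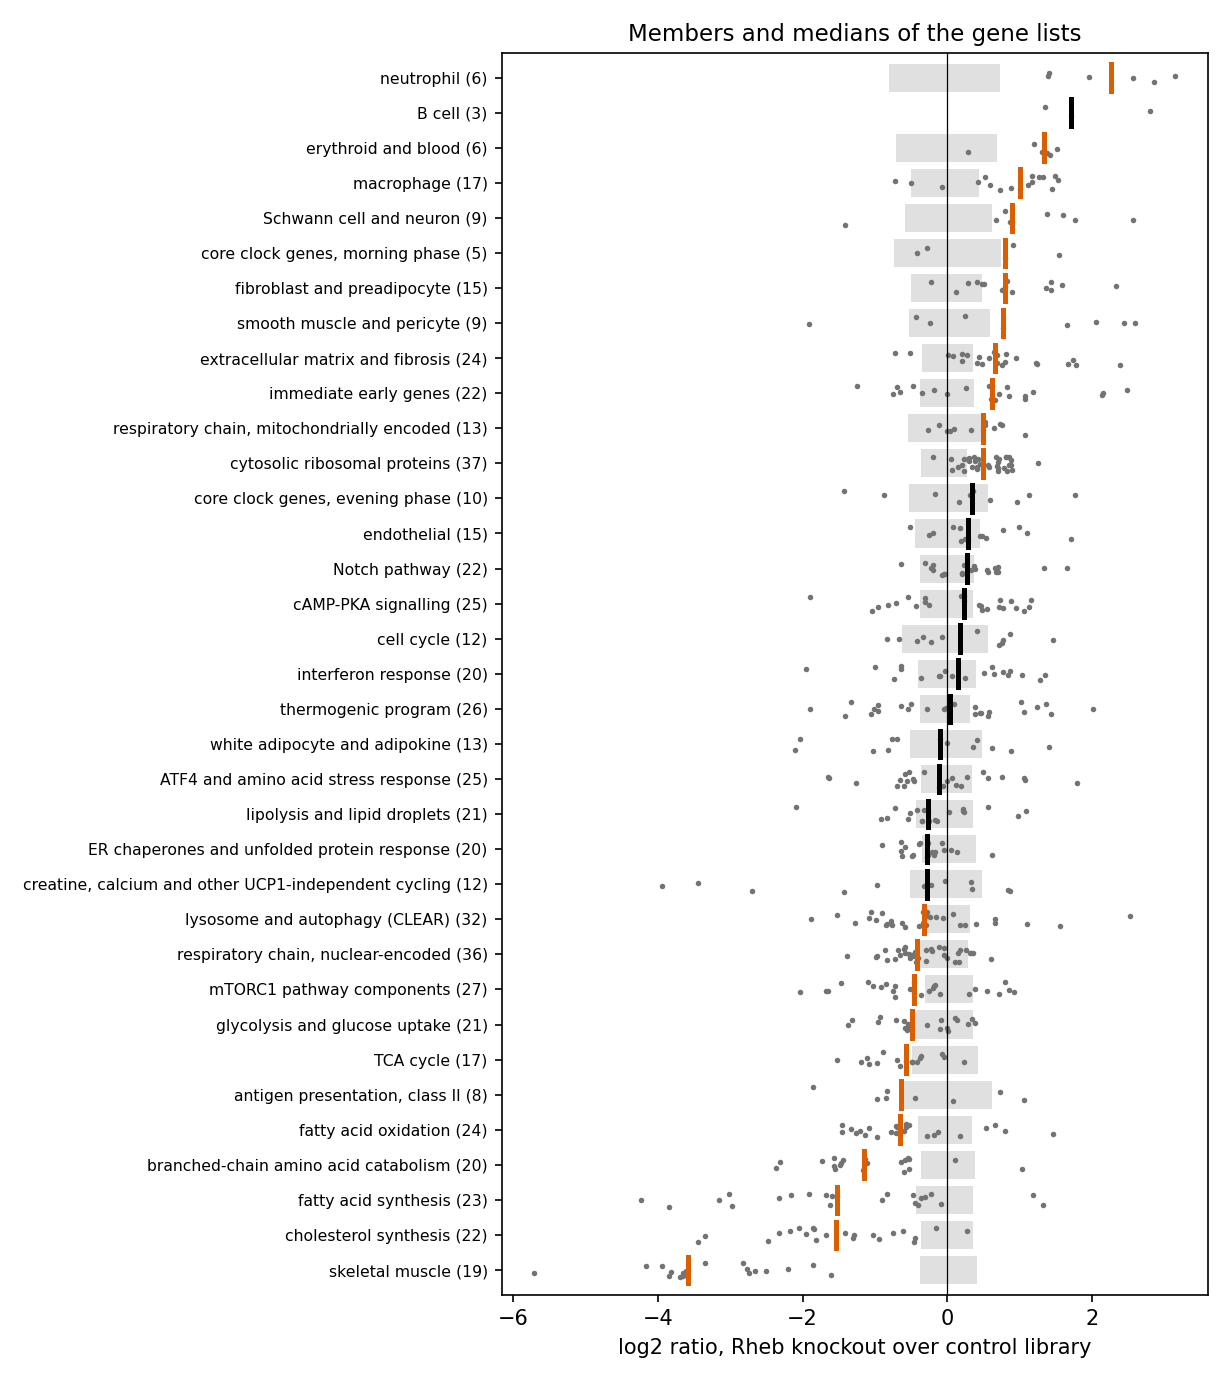
Log2 ratio of the Rheb knockout over the control library (horizontal) for the measured members (grey points, number in brackets) of each gene list except the sex markers and the T and NK cell list; upright bars are list medians, orange where they stand apart, and grey boxes hold the middle 95% of medians of 10000 random lists matched on expression (none for the B cell list, with 3 members). Skeletal muscle (median -3.58), cholesterol synthesis (-1.54) and fatty acid synthesis (-1.53) have the lowest medians and the neutrophil list (2.26) the highest, while the thermogenic program (0.03) lies inside its box.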

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

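With 1 library per group no library could be left out, and no paired analysis was possible because each group has a single pooled library. The Rheb ratio stayed between 0.505 (total counts) and 0.574 (total counts without the 20 highest genes), within its counting interval. The main counts of 1201 higher and 1294 lower genes moved by over 1.5 times under 4 settings. They were 603 and 590 with a filter of 10 CPM, 771 and 838 with a pseudocount of 2, 2839 and 2839 at a threshold of 1.5-fold, and 302 and 494 at 3-fold. The last 2 follow from another threshold, and a larger pseudocount shrinks the ratios of low genes. The filter of 10 CPM kept 7745 genes, and both counts fell by a larger share than the number of genes did. Other settings kept both counts within 1.5 times, but total counts gave 34.7% higher among genes beyond the rule against 48.1% with TMM. DESeq2 size factors came out equal for both libraries. The planned comparisons with the authors' normalized values and calls were not run, since the table used here holds counts. Of 344 list percentiles under alternatives, 326 kept their side of the range, 14 no longer stood apart and 4 came to stand apart. Most are given with their lists. The others are the morning clock list (96.9 after the GC correction), the lysosome list (2.77 with a pseudocount of 2, 2.54 without matching, 2.66 without Atp6v1h) and the smooth muscle list (95.1 without Myh11). The thermogenic median, which did not stand apart, was the only list median to change sign with the scaling. The cAMP-PKA list stood apart after the GC correction (98.2). The numbers of lists above and below ranged from 8 to 12 and from 10 to 11. No named gene with an interval that excluded 1 changed sign under another scaling. Even so, 114 of their log2 ratios under other scalings lay outside the counting interval of the gene, and 351 lay inside. These ratios hold the pseudocount, which the intervals do not. Ucp1 lay outside its interval under 2 scalings and inside under 1. The intervals of single genes thus do not cover the choice of scaling. Depth limits genes with few counts, such as Gpnmb, Timp1 and Retnlg, but the missing replicates limit every gene.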

Other observations

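The gene families and all tests of explanations in this part were chosen after the values they concern had been seen, whereas the gene lists they use were fixed before. Protein-coding genes were also grouped by the letter stem of their symbols into 199 families of at least 8 members. Each was compared with 10000 random lists matched on expression, without a correction for GC content. If genes varied independently, about 9.95 families would lie outside the middle 95% by chance, and 18 lay below and 17 above. All 12 major urinary protein (Mup) genes were lower in the knockout library, with a median log2 ratio of -3.68, although reads of these paralogs cannot be assigned with certainty. All 8 measured histone cluster (Hist) genes were lower, with a median of -1.77, among them Hist1h2bc (1761 and 292 counts) and Hist1h1c (1820 and 502 counts). How fully the library preparation captures histone transcripts was not tested, so these counts may not follow histone expression. The cell cycle list had a median of 0.17, and a link between the 2 groups was not tested. Aldehyde dehydrogenases (Aldh) were lower in 9 of 14 cases and higher in none (median -0.94), including Aldh2 with 9100 and 2100 counts and Aldh1a7 with 1353 and 98 counts. Aldo-keto reductases (Akr) were lower in 5 of 8 cases and higher in none (median -1.01).

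Families of genes for mitochondrial ribosomal proteins had medians below 0, though most members passed no size rule. Large-subunit Mrpl genes were lower in 19 of 48 cases and higher in none (median -0.38, percentile 0.030), and Mrps genes were lower in 8 of 29 and higher in 1 (median -0.34, percentile 0.92). Higher families were collagens (Col, 15 of 29 higher and none lower, median 0.61, with 10 of them also in the fixed lists), Adam proteases (10 of 14 higher and 1 lower, median 0.74), Chd chromatin remodellers (7 of 9 higher and none lower, median 0.81) and zinc finger genes named Zfp (87 of 307 higher and 41 lower, median 0.23). At the same 1.5-fold rule 2839 of all 12973 kept genes were higher and 2839 lower, a share to which the Zfp and Mrps counts lie close.

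The first pattern is that sex-linked transcripts of the control library go against its male label. Loss of Y-linked reads in mapping is argued against as the sole explanation by the 7452 Xist counts of that library (exact Poisson 95% interval 7284 to 7623). Male tissue barely expresses Xist. Over 4 Y-linked genes the control library had 1 count and the knockout library 4827, so reads of these genes could be mapped and counted. A pool of female mice is a candidate explanation: 6 genes known to escape X inactivation had a median log2 ratio of -0.91, at percentile 0.77 of random X-linked lists, and Y-linked reads reached at most 0.114% of the knockout level. Whether sex rather than genotype set the other differences cannot be told apart, since there is 1 library of each kind; 96.6% of the genes beyond the 2-fold rule were autosomal, which decides nothing.

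A further pattern is the lower level of lipid synthesis genes in the knockout library. Muscle RNA in the control library is argued against as the source of the summed loss of the fatty acid synthesis list. That list lost 10.4 times as much CPM (37870) as the skeletal muscle list (3633), which includes the abundant muscle transcripts Acta1 and Ckm. Scd1 holds a large part of this sum (17163 CPM in the control and 1924 CPM in the knockout library). The comparison cannot decide for members with smaller losses, such as Scd2 (527.8 and 27.6 CPM). Cholesterol synthesis genes were not put through it. A lower share of brown adipocytes is argued against as the whole cause, because the lower quartile of the lipolysis and lipid droplet list was -0.51, above the fatty acid synthesis median of -1.53. GC content is argued against, although ratios followed it weakly across genes (Spearman rho 0.164, genes not being independent), because the median stayed at -1.40 after that trend was removed, and the cholesterol synthesis median at -1.53. Genotype, sex, and feeding or handling of the pooled mice stay open and were not tested.

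The last pattern is the higher level of neutrophil, erythroid, macrophage, stromal and nerve markers in the knockout library. A lower adipocyte share that raises all other types alike is argued against as the sole cause for the erythroid markers only. The lower quartile of the erythroid list lay 0.57 log2 units above the upper quartile of the endothelial list. Without the filter it lay 0.13 above it, the lowest value over the settings. For the neutrophil list this gap was 0.89, but -0.18 without the filter, so that list decides nothing. The lower quartiles of the macrophage (0.52), fibroblast (0.44) and smooth muscle (-0.24) lists lay below the endothelial upper quartile (0.65). For these markers, and for Schwann cell markers (lower quartile 0.80, and 0.34 without the filter), a lower adipocyte share stays open. Blood left in the tissue, which lacks these transcripts, is argued against for Schwann cell markers, whose list lay at percentile 98.2 or higher in every setting, and for fibroblast markers, whose lower quartile was 0.44 and stayed above 0 in every setting (0.20 with a filter of 10 CPM, where the list no longer stood apart). For erythroid and neutrophil markers it stays open: their medians differed by 0.92, and by 0.14 without the filter, and the ratio of neutrophil to globin RNA in the blood of these mice is not known.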
